A study of Mus musculus with 18 samples.

How the data were processed

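RNA from primary mouse pre-B cells was measured on 1-colour Illumina MouseRef-8 BeadChips, 18 arrays in all. Per the labels' protocols, bone marrow of mice on a mixed C57BL/6 and BALB/c background was cultured in IL-7, RNA was isolated from the cells in IL-7 or after withdrawal of IL-7, and labelled with biotin. The design text speaks of independent cultures of each genotype, so the replicates were taken as separate cultures. Groups and replicate numbers came from the sample titles; the genotype field of the labels writes the Art:Nfkb2 genotype without the mark of a knockout on Nfkb2, and the titles were followed.

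The deposited table of probe signals holds an intensity for each of 25697 probes, not normalized and all above 0, and a detection p-value per probe and array, per the file headers. The deposited series matrix holds a second intensity per probe. From its values, it is linear, background-subtracted (29.5% to 29.7% of values below 0) and quantile-normalized, with column medians of 19.99 to 20.29 and a rank correlation of 1 with the same array's signal; it is not centred per gene. The exact steps are not given in the sources used here. Per the submitters' processing notes, Partek and GenomeStudio were used, without version or role. No slide was named, so no block on slides could be fitted. Columns of per-sample values not used: 0. Median raw signal per array was 129.3 to 163.1.

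Signals were background-corrected by normexp with the detection p-values, quantile-normalized and put on the log2 scale with an offset of 16 (neqc of limma 3.58.1, in R 4.3.3). Because of the offset, differences of dim genes are understated. Of the probes, 23978 had 1 gene symbol, 0 had several and 1719 were unnamed; 23962 matched the reference table by Entrez gene and 0 symbols were updated. Probes detected (detection p below 0.01) on at least 3 arrays were kept (11356), and the brightest probe stood for each gene, which left 8446 entries, 673 of them named by probe ID. For 2086 genes more than 1 probe passed. No reference genome was used; gene order for neighbouring genes came from the reference table without coordinates being given here.

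A linear model over the 6 groups was fitted to every gene with lmFit and eBayes, and p-values were adjusted by the Benjamini-Hochberg method per comparison, with a threshold of 0.05 and a second count at 2-fold. All tests were two-sided. The 10 comparisons were withdrawal in each genotype, the genotypes against each other after withdrawal and in IL-7, and the differences of the withdrawal response. The word called refers to this threshold; SE is the moderated standard error. A gene detected on no array of a group has only a bound. It compares the bright group's mean with the dim group's mean of, per array, the higher of the lowest normalized signal among detected probes and the gene's own. No fold is given where neither group detected the gene. A list's median is also given with such genes at their bound, or at 0 where neither group detected the gene or the bound lies under 1.

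There were 21 gene lists: pre-BCR and BCR signalling, NF-kB, p53 targets, DNA break repair, IL-7 receptor and STAT5, proliferation, glycolysis, pre-B differentiation, BCL2 family, MHC class II, adhesion, interferon-stimulated genes, study genes, and markers of myeloid, T, NK, erythroid, mast, stromal, mature B and early progenitor cells. They were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists, with the correlation estimated as an alternative, and with fry, which tests whether a list's genes move on balance one way. Of the camera calls, those that held with an estimated correlation were proliferation on withdrawal in Art:Nfkb2-labelled cells; NF-kB, p53 and study genes in Art-labelled against Rag-labelled cells, after withdrawal and in IL-7; the same lists with adhesion and MHC class II in Art:Nfkb2-labelled against Rag-labelled withdrawn cells; and NF-kB in Art:Nfkb2-labelled against Art-labelled cells in IL-7. The study genes came from knowledge of the published study, and some of them also stand in other lists. Nfkb2, Cd40, Pim2 and Bcl3 are in NF-kB, Syk and Blnk in pre-BCR signalling, and Cd40, Cd69 and Swap70 in adhesion. A list's counts were also adjusted over the list alone.

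The genes named are the targeted genes, the study genes, the 10 largest changes per direction in the comparisons of Art-labelled with Rag-labelled and Art:Nfkb2-labelled with Art-labelled withdrawn cells and the 5 largest per direction in the others, among called genes whose groups do not overlap, and members of the lists. A result that this rule would name is not reported here. The groups, tests of the comparisons, lists and naming rule were fixed before the data were examined, as were the alternatives except those without the Y-positive culture, with the myeloid covariate and without Pgk1. The tests of genes near the targeted loci were also chosen later.

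Same-numbered arrays of a genotype, which the titles number alike in IL-7 and after withdrawal, deviated together from their group means: all 9 correlations lay between 0.37 and 0.59, above the limit of 0.1 set for pairing. The culture was therefore fitted as a block in an alternative for the withdrawal and interaction comparisons. Alternatives also covered the background correction, the scaling, the deposited matrix, the filter on dim probes, all probes, the variance model, array weights, the samples in the fit and each array left out in turn.

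The procedure was tested on simulated data built on the comparison of Art-labelled with Rag-labelled withdrawn cells with 8446 genes. Of genes changed by 0.5, 1 and 2 on the log2 scale, limma recovered 26.9% (18 of 67), 86.6% (58 of 67) and 100% (66 of 66). There were 9 false calls among 151. The simulation changed fewer genes than the 1607 called in that comparison and drew the arrays of a culture independently. These rates therefore need not hold for the data. For comparisons that share arrays, 100 simulations of unchanged groups gave the value expected where no gene changes.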

Results

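The data comprised 18 arrays of RNA from primary mouse pre-B cells, the bone marrow stage at which a B-cell precursor has a heavy chain and is about to recombine its light-chain genes. The cells carried a rearranged heavy-chain transgene and a Bcl2 transgene, which lets them outlive the loss of a survival cytokine, and were grown in interleukin 7 (IL-7), the growth factor of early B cells. There were 9 cultures, 3 of each of 3 genotypes, and each culture gave 2 arrays: 1 in IL-7 (day 0) and 1 at 2 days after IL-7 was withdrawn, giving 6 groups of 3 arrays. By the labels, Rag-labelled cells lack RAG1 and cannot cut their antigen receptor genes. Art-labelled cells lack Artemis, the nuclease that opens the hairpin ends RAG leaves, so that RAG breaks stay unrepaired. By the same labels, Art:Nfkb2-labelled cells lack Artemis and Nfkb2, a subunit of the noncanonical NF-kB pathway. Per the series title, the question was how DNA double strand breaks made by RAG relate to signalling from the pre-B-cell receptor. Between 10091 and 10894 of 25697 probes per array were detected (39.3% to 42.4%), and 8446 genes were tested. Replicates of a group correlated at 0.979 to 0.993. With 3 arrays per group, the number of arrays limits the precision.

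The targeted genes were read first. Rag1, which encodes the catalytic recombinase subunit, was brightest on Rag-labelled arrays, at a log2 signal of 12.72 ± 0.27 (SD, n = 3) after withdrawal against 11.37 ± 0.19 in Art-labelled and 11.03 ± 0.15 in Art:Nfkb2-labelled cells. Its partner Rag2 was detected on all 3 withdrawn Rag-labelled arrays (7.47 ± 0.46) and on no withdrawn array of the other genotypes. Nfkb2 was not lower on Art:Nfkb2-labelled arrays: it read 9.21 ± 0.18 after withdrawal, against 8.80 ± 0.05 in Art-labelled and 7.56 ± 0.09 in Rag-labelled cells. Where these probes lie relative to the deleted parts is not given in the sources used here, so the levels check neither genotype label, and the groups are named by label throughout. Dclre1c, which encodes Artemis, was not analysed here.

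Withdrawal of IL-7 lowered the genes of cell division in all 3 genotypes. Of 30 tested proliferation genes, 29 fell in Rag-labelled, 29 in Art-labelled and 28 in Art:Nfkb2-labelled cells. The list medians were -2.50, -2.65 and -2.51 on the log2 scale, and -2.41, -2.58 and -2.42 with undetected genes at their bound. Birc5, the survivin gene of dividing cells, changed by -3.65, -3.77 and -5.56 in the same order, and Top2a, the topoisomerase that untangles replicated chromosomes, by -3.50, -3.45 and -5.15. Pclaf, a replication clamp partner, changed by -4.33 in Rag-labelled and -4.33 in Art-labelled cells, and was at least 59.1-fold lower in Art:Nfkb2-labelled cells, where it dropped out of detection. The camera test placed the list below the other genes with adjusted p of 1.02e-26, 5.95e-27 and 2.35e-28. With an estimated correlation the adjusted p was 0.0567, 0.055 and 0.046.

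Some genes that IL-7 drives through STAT5 fell. Cish, a feedback inhibitor of cytokine receptors, changed by -2.79, -3.26 and -3.22 in Rag-labelled, Art-labelled and Art:Nfkb2-labelled cells. Socs2, of the same inhibitor family, changed by -2.55, -3.36 and -3.46, and Ccnd2, a cyclin that drives entry into the cell cycle, by -4.13, -2.96 and -3.22. In the IL-7 receptor and STAT5 list 7, 8 and 9 of 19 genes fell while 1, 5 and 2 rose. Adjusted over the list alone, 7, 9 and 10 fell and 1, 5 and 4 rose. The list medians were -0.19, -0.28 and -0.47 (-0.09, -0.28 and -0.35 with undetected genes at their bound), with camera adjusted p of 0.00859, 0.00515 and 0.00257 (adjusted p = 0.112, 0.0604 and 0.0512 with an estimated correlation). Glycolytic enzymes fell as well, 9, 10 and 9 of 14, while in Art:Nfkb2-labelled cells 4 rose, with medians of -0.69, -1.04 and -0.74 and camera adjusted p of 8.59e-05, 2.51e-06 and 0.00468. With an estimated correlation these were adjusted p = 0.128, 0.0604 and 0.318. Ldha, which turns pyruvate into lactate, changed by -1.99, -2.16 and -1.95.

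Myl10, which encodes a myosin regulatory light chain, fell steeply in each genotype. It was at least 281.3-fold lower after withdrawal in Rag-labelled cells and at least 223.3-fold lower in Art:Nfkb2-labelled cells, and in Art-labelled cells it was 169.3-fold lower (limma adjusted p = 1.23e-13). Gldc, the glycine decarboxylase of mitochondria, was at least 28.8-fold lower in Rag-labelled and at least 23.3-fold lower in Art-labelled cells. Tmprss3, a membrane serine protease, was at least 34.8-fold lower in Art-labelled and at least 23.2-fold lower in Art:Nfkb2-labelled cells. Vpreb1, a surrogate light chain of the pre-B-cell receptor, changed by -1.70, -2.89 and -4.09.

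Some genes of the next developmental step rose. Bcl6, a repressor that protects pre-B cells during recombination, rose by 1.17, 1.81 and 1.11. Rag1 rose by 1.11, 1.92 and 1.28, but it is lost by label in Rag-labelled cells, so its value there does not speak to differentiation. Syk, the kinase downstream of the pre-B-cell receptor, rose by 0.72, 0.67 and 0.65 (SE 0.13 in each). Of 23 genes of pre-B differentiation and light-chain recombination, a list that includes Rag1, 10, 10 and 9 rose while 2, 1 and 3 fell. Adjusted over the list alone, 11 rose in Art-labelled and 10 in Art:Nfkb2-labelled cells. Camera gave adjusted p of 0.0445, 0.0358 and 0.0245, and adjusted p = 0.43, 0.317 and 0.318 with an estimated correlation. The call in Rag-labelled cells was lost without IL-7 array 1 (0.0607) or 2 (0.0821) or withdrawn array 1 (0.073) or 3 (0.0682), and that in Art-labelled cells without withdrawn array 1 (0.0534). Among the largest rises was Il4i1, an amino acid oxidase of activated B cells, which rose by 2.36, 3.06 and 2.19. Marchf1, a ubiquitin ligase that turns over MHC class II molecules, rose by 2.82 in Art-labelled and 1.92 in Art:Nfkb2-labelled cells.

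More NF-kB pathway genes and p53 targets rose than fell on withdrawal, although camera did not call either list in all 3 genotypes. Of 31 NF-kB genes, 16, 20 and 17 rose and 4, 4 and 5 fell in Rag-labelled, Art-labelled and Art:Nfkb2-labelled cells, with medians of 0.35, 0.60 and 0.41. Ltb, a lymphotoxin gene that NF-kB induces, rose by 1.01, 1.57 and 1.09, and Cd40, the receptor for T-cell help, by 0.97, 1.20 and 0.86. Camera called this list in Rag-labelled (adjusted p = 0.0445; adjusted p = 0.43 with an estimated correlation) and Art-labelled cells (0.00235; adjusted p = 0.0977 with an estimated correlation), and not in Art:Nfkb2-labelled cells (0.0851). The Rag-labelled call was lost without IL-7 array 1 (0.0609) or 2 (0.0662) or withdrawn array 2 (0.0777) or 3 (0.078). Of 28 p53 targets, 9, 18 and 17 rose, and the list was called in Art-labelled (median 0.74, adjusted p = 0.000307) and Art:Nfkb2-labelled cells (0.56, adjusted p = 0.000969). With an estimated correlation these were adjusted p = 0.0868 and 0.151. In Rag-labelled cells the median was 0.26 (adjusted p = 0.0733). Fry called both the NF-kB and the p53 list in all 3 genotypes (adjusted p up to 0.000572). MHC class II genes, which present antigen to helper T cells, rose in 10 of 12 in Art-labelled and 9 of 12 in Art:Nfkb2-labelled cells, with medians of 1.04 and 0.84 (adjusted p = 0.00281 and 0.00223; adjusted p = 0.317 and 0.318 with an estimated correlation). In Rag-labelled cells 3 rose (median 0.24, adjusted p = 0.492).

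In counts, withdrawal changed 3753 genes in Rag-labelled cells (2111 higher, 1642 lower), 3803 in Art-labelled cells (2215 and 1588) and 3428 in Art:Nfkb2-labelled cells (1920 and 1508). Changes of at least 2-fold went mostly down: 616 fell and 135 rose in Rag-labelled, 612 and 252 in Art-labelled, and 587 and 143 in Art:Nfkb2-labelled cells. Of the 2688 genes called in both Rag-labelled and Art-labelled cells, 2662 moved the same way, where independent lists of these sizes would share 862.3. Scaling arrays to a common median in place of quantile normalization moved the median of all genes from 0.10 to -0.01 in Rag-labelled cells and the higher share of the calls from 56.2% to 33.8%. In Art:Nfkb2-labelled cells it moved them the other way, from 0.09 to 0.18 and from 56% to 65.3%. With both arrays of the Art:Nfkb2-labelled culture that carried Y-linked signal left out, 2261 genes were called in that genotype.

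**Figure D1:**
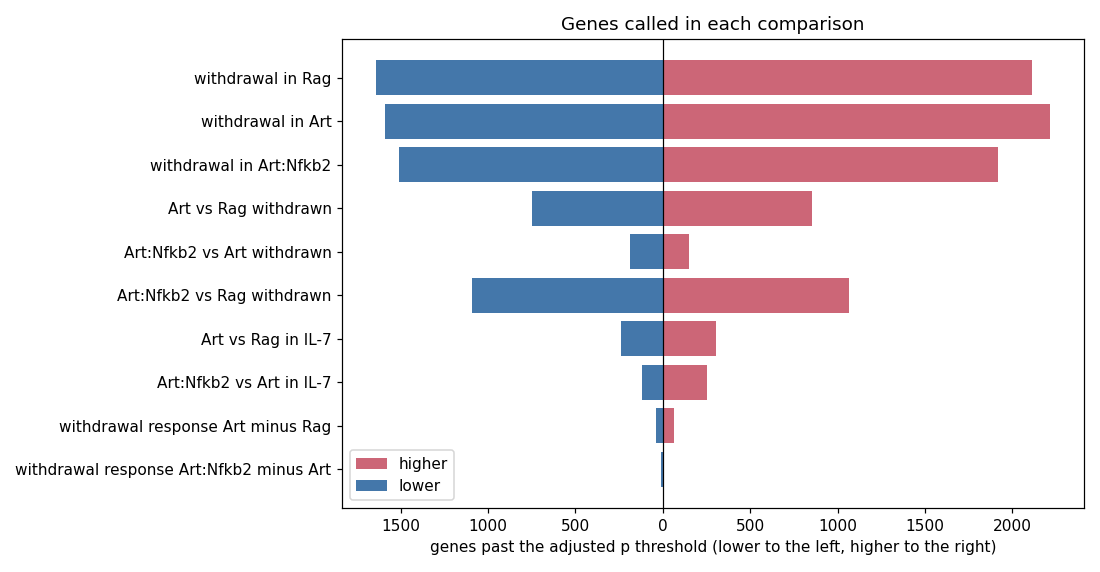
Numbers of genes called in each of the 10 comparisons (limma, Benjamini-Hochberg adjusted p below 0.05), with genes higher and lower drawn apart. The withdrawal comparisons call 3428 to 3803 genes, Art-labelled against Rag-labelled cells after withdrawal 1607, and Art:Nfkb2-labelled against Art-labelled cells after withdrawal 337.

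The comparison of Art-labelled with Rag-labelled cells after withdrawal was used to ask what unrepaired RAG breaks change. By their labels, both genotypes lack a complete receptor rearrangement and differ in whether breaks can be made. Breaks were not measured here, and Rag2 was detected on no withdrawn Art-labelled array. The genotypes also differed in sex-linked signal, and 417 of the genes called here already differed the same way in IL-7. The comparison therefore does not isolate the breaks. Art-labelled cells had higher NF-kB and p53 target genes. Bcl3, an NF-kB cofactor, read 10.32 ± 0.003 (SD, n = 3) against 7.72 ± 0.34, a 6.07-fold difference (log2 difference 2.60 ± 0.15 SE, limma adjusted p = 1.88e-08). Cdkn1a, the p21 inhibitor of the cell cycle, was 5.71-fold higher (2.51 ± 0.26 SE, adjusted p = 4.92e-06). Spic, a transcription factor of the ETS family related to PU.1, was detected in no other group and reached 7.18 ± 0.11 in Art-labelled withdrawn cells, at least 1.80-fold above Rag-labelled cells (adjusted p = 1.85e-08). Syk was lower, by a log2 difference of -0.57 ± 0.13 (SE, adjusted p = 0.0129), and its call was lost without Rag-labelled withdrawn array 3 (adjusted p = 0.0648) or Art-labelled withdrawn array 2 (0.0563).

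Of 31 NF-kB genes, 18 were higher and 1 lower, and 19 and 1 adjusted over the list alone. The median was 0.59 (0.45 with undetected genes at their bound) and camera gave an adjusted p of 3.11e-08, which held with an estimated correlation (adjusted p = 0.0101). Ltb was 7.42-fold higher, Pim2, a survival kinase, 4.59-fold, Cd83, a maturation marker, 3.53-fold, and Cd40 differed by 1.82 on the log2 scale (adjusted p = 2.91e-05). The lower member was Gadd45b, a stress sensor, at -0.88. Nfkb2 itself was 2.36-fold higher. Bcl3, Pim2, Cd40 and Nfkb2 are also study genes, so this list is not fully independent of the published study.

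Of 28 p53 targets, 16 were higher and 3 lower, with 17 and 3 adjusted over the list alone, a median of 0.60 and a camera adjusted p of 5.99e-09, which held with an estimated correlation (adjusted p = 0.0101). The higher members included Phlda3, an inhibitor of Akt, at 6.33-fold, the death receptor gene Fas at 4.93-fold, and Zmat3, an RNA-binding regulator, at 3.84-fold. Pmaip1 and Bbc3, the killers Noxa and Puma of the BCL2 family, differed by 1.75 and 1.52. The lower members were Gadd45a at -1.37, the nucleotide supplier Rrm2b at -0.98 and the damage sensor Xpc at -0.86. In the BCL2 family 4 of 11 genes were higher and 1 lower (5 and 1 adjusted over the list alone), with a median of 0.20 and an adjusted p of 0.0169 (adjusted p = 0.0564 with an estimated correlation). Bcl2l11, the death promoter Bim, was higher by 0.93 and Bcl2l1, the survival gene for Bcl-xL, lower at -1.01.

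MHC class II genes were higher in 9 of 12, and in 10 adjusted over the list alone. The median was 1.36, the camera adjusted p 8.59e-08, and adjusted p = 0.0814 with an estimated correlation. H2-DMa, which loads peptide onto class II molecules, read 11.57 ± 0.18 against 9.92 ± 0.04, and Cd74, the invariant chain, differed by 1.31. Markers of myeloid cells, which also carry class II genes, did not pass: 0 of 17 were called by limma in either direction, and 0 at an unadjusted p under 0.05, with a median of -0.28 (0 with undetected genes at their bound, as 10 of the 17 were not detected in a group) and a camera adjusted p of 0.531.

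The genes with the largest differences included sex-linked ones. Xist, the X-inactivation RNA, was at least 22.7-fold higher in Art-labelled cells, and Eif2s3y and Kdm5d, which lie on the Y chromosome, were at least 25.03-fold and 3.12-fold lower. Slc47a1, a transporter of organic cations, was 60.4-fold higher (5.92 ± 0.22 SE, adjusted p = 2.12e-10). Cd80, a ligand that costimulates T cells, was 12.2-fold higher (adjusted p = 9.56e-07) and Dnase1l3, a secreted nuclease, 8.38-fold (adjusted p = 1.16e-07). The Wnt ligand gene Wnt10b, the Wnt inhibitor gene Lrp4 and Tnfsf8, the ligand of CD30, were at least 4.81-fold, 6.35-fold and 3.80-fold higher. Asb2, part of a ubiquitin ligase, was 22.8-fold lower (-4.51 ± 0.34 SE, adjusted p = 3.07e-07), and the kinase gene Camk2b at least 10.2-fold lower. The receptor kinase gene Ret was 9.81-fold lower and Gng4, a G-protein subunit, at least 4.49-fold. Rcan2, a calcineurin inhibitor, was at least 3.21-fold lower. Gdpd3, a lysophospholipase, differed by -3.52, and its call (adjusted p = 0.0393) was lost without Rag-labelled withdrawn array 1 (0.147) or 2 (0.135) and without Art-labelled withdrawn array 1 (0.0876), 2 (0.103) or 3 (0.0809). Of these ranked genes, 3 more entries, 2 higher and 1 lower, had no gene symbol.

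Other lists followed. Of 23 genes of pre-B differentiation, 4 were higher and 6 lower (4 and 12 adjusted over the list alone), with a median of -0.30 and an adjusted p of 0.0689. Rag1, lost by label in Rag-labelled cells, was lower at -1.35, so its value does not speak to differentiation. Klf2, a factor that keeps lymphocytes quiescent, was lower at -1.05. In the pre-B-cell receptor list 2 of 21 were higher and 5 lower, with an adjusted p of 0.272. Vpreb1 was lower at -1.24, and Blnk, the adaptor beside Syk, read -0.40 (adjusted p = 0.14). Adhesion and costimulation genes were higher in 6 of 15 and lower in 1 (adjusted p = 0.0863). Fry called the adhesion list (adjusted p = 0.000187) and the pre-B differentiation list (0.0181), which camera did not. Proliferation (0.564), the IL-7 receptor and STAT5 list (0.533), interferon-stimulated genes (0.339), glycolysis (0.967) and DNA break repair (0.967) were not called. The glycolysis median was -0.11 and its mean 0.06, and in the DNA break repair list the median of -0.01 stood against a camera direction of up. Of 11 genes taken from knowledge of the published study of these samples, 6 were higher and 1 lower, also adjusted over the list alone (median 1.14, adjusted p = 0.00025; adjusted p = 0.0101 with an estimated correlation), and this list is not independent evidence. Its member Swap70, a signalling adaptor of B cells, differed by 1.14, while Bclaf1 (-0.23, adjusted p = 0.256) and Cd69 (0.43, adjusted p = 0.225) were not called. Both were called without Rag-labelled withdrawn array 2, Bclaf1 with an adjusted p of 0.0447 and Cd69 with 0.0256.

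In all, 1607 genes differed between Art-labelled and Rag-labelled cells after withdrawal, 856 higher and 751 lower, and 440 by at least 2-fold (260 higher, 180 lower). Fitted on the arrays of these groups alone, limma called 980.

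**Figure D2:**
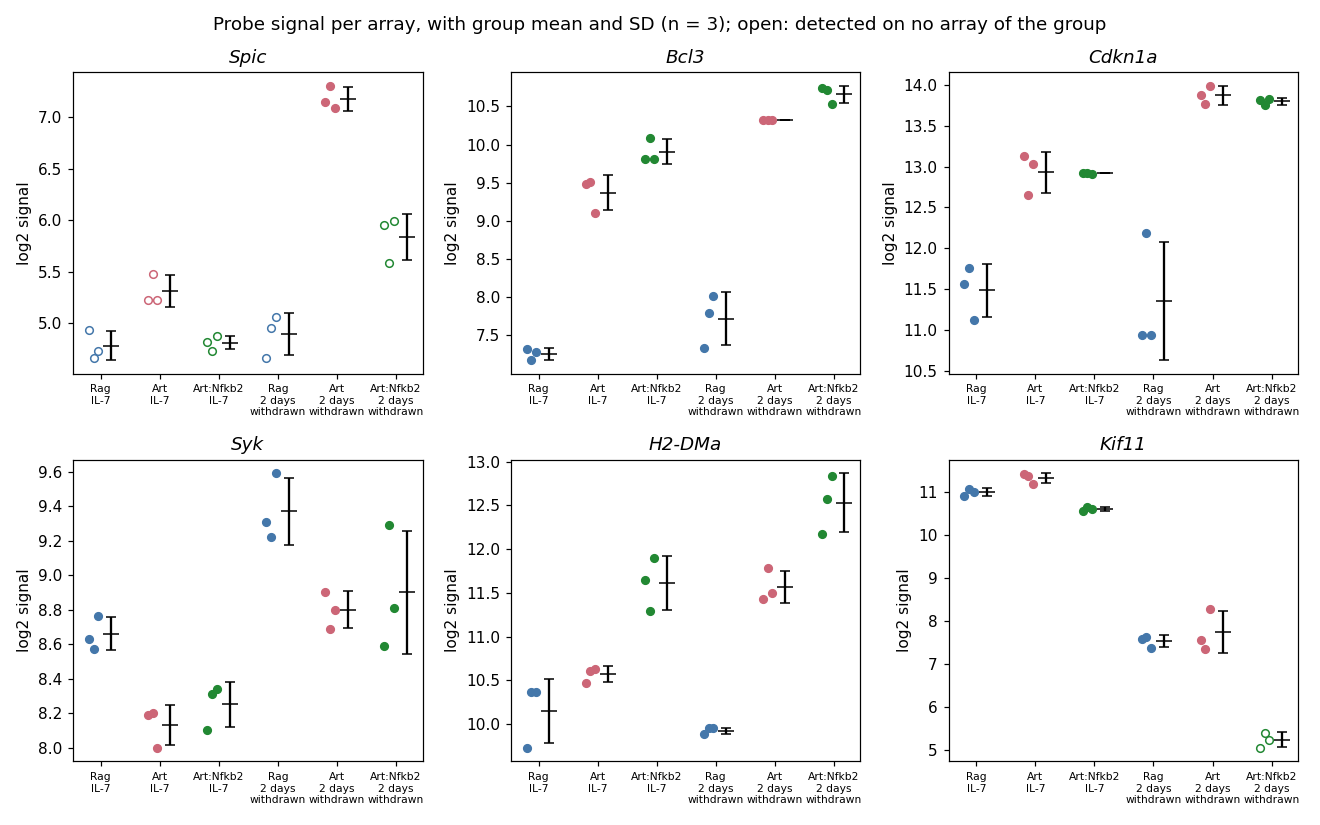
Normalized log2 signal of Spic, Bcl3, Cdkn1a, Syk, H2-DMa and Kif11 on each of the 18 arrays by genotype label and day, with the mean and SD of each group of 3, open where the gene was detected on no array of the group. Spic is filled in Art-labelled withdrawn cells, at a mean of 7.18, and Kif11 in Art:Nfkb2-labelled withdrawn cells lies at 5.23 and is open.

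The comparison of Art:Nfkb2-labelled with Art-labelled cells after withdrawal asks which of these genes differ where Nfkb2 is lost by label. In Art:Nfkb2-labelled cells 13 of 30 proliferation genes were lower and 5 of 12 MHC class II genes higher, while Bcl3 and the p53 targets showed no called difference. Both lists lost their camera call with an estimated correlation (adjusted p = 0.2 and 0.111), and myeloid markers were higher beside the class II genes (1 of 17, 8 adjusted over the list alone). Kif11, a spindle motor, was at least 2.72-fold lower and dropped out of detection at 5.23 ± 0.18 (SD, n = 3) against 7.74 ± 0.49 (adjusted p = 3.8e-07). Spic was at least 1.85-fold lower (adjusted p = 1.12e-05), falling to 5.84 ± 0.22, below detection. H2-DMa was higher by 0.96, at 12.53 ± 0.34 against 11.57 ± 0.18. Bcl3 read 0.34 (adjusted p = 0.299), Cd40 0.24 (0.737), Pim2 -0.27 (0.726), Swap70 0.34 (0.285), Syk 0.10 (0.868) and Blnk -0.05 (0.961). Nfkb2 read 0.41 (0.0718), and without Art:Nfkb2-labelled withdrawn array 3 its adjusted p was 0.0342.

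Of 30 proliferation genes, 13 were lower and 1 higher, and 15 and 3 adjusted over the list alone. The median was -0.47 (-0.22 with undetected genes at their bound), the camera adjusted p 1.19e-09, and adjusted p = 0.2 with an estimated correlation. Cdk1, the kinase that starts mitosis, Birc5 and Top2a differed by -2.18, -2.10 and -2.07. Among other named genes, the spindle motor gene Kif18b was 6.20-fold lower (adjusted p = 2.25e-06), Kif2c, of the same family, at least 3.94-fold lower and the spindle protein gene Nusap1 4.88-fold lower. Pbk, a mitotic kinase, and Pif1, a DNA helicase, were at least 3.43-fold and 3.23-fold lower. The higher member was Tk1, the thymidine kinase of dividing cells, at 1.46. Kansl1l (-2.38, adjusted p = 0.0123) lost its call without Art-labelled withdrawn array 1 (0.0543). Efna5, an ephrin (-2.36, adjusted p = 0.0429), lost its call without Art-labelled withdrawn array 1 (0.117), 2 (0.152) or 3 (0.091) and without Art:Nfkb2-labelled withdrawn array 1 (0.15), 2 (0.104) or 3 (0.0957). A probe with no gene symbol differed by -3.40.

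MHC class II genes were higher in 5 of 12, and in 9 adjusted over the list alone (median 0.74, camera adjusted p = 1.19e-09; adjusted p = 0.111 with an estimated correlation). Myeloid markers were higher with them: 1 of 17, and 8 adjusted over the list alone, with a median of 0.66 (0 with undetected genes at their bound, which 10 of the 17 were) and an adjusted p of 0.000316 (adjusted p = 0.514 with an estimated correlation). The called myeloid marker was Fcgr3, an Fc receptor, at least 3.56-fold higher. Adhesion and costimulation genes were higher in 2 of 15 (median 0.16, adjusted p = 0.01; adjusted p = 0.111 with an estimated correlation), among them Gpr183, a migration receptor, at 1.35 and Cxcr5, which guides B cells into follicles, at 1.22. Mature B-cell markers were higher in 3 of 9 (adjusted p = 0.0321; adjusted p = 0.111 with an estimated correlation), a call lost without Art-labelled withdrawn array 3 (0.0631). With the myeloid signal as a covariate, a choice made after the data were seen, the adhesion list had an adjusted p of 0.256.

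NF-kB genes were not lower: 1 of 31 was higher (4 adjusted over the list alone) and 0 were lower by limma, 0 also at an unadjusted p under 0.05, at a median of 0.16 (adjusted p = 0.0297; adjusted p = 0.299 with an estimated correlation). The call was lost without Art-labelled withdrawn array 3 (0.0537), with median scaling (0.0597) and with the myeloid covariate (0.311). Of 28 p53 targets limma called 0 in either direction, and 2 higher and 2 lower at an unadjusted p under 0.05 (median -0.11, camera adjusted p = 0.241). Among the study genes 1 was lower, Spic (adjusted p = 0.652 for the list); their median was 0.10 and their mean -0.001. The pre-B-cell receptor list (1 lower, 0.0852), whose median of -0.12 was 0.005 under median scaling, and the pre-B differentiation list (3 higher, 0.177) were not called. Neither were interferon-stimulated genes (0.0721) nor the IL-7 receptor list (0.525).

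The probe of Pgk1, a glycolytic kinase, read at least 6.63-fold higher (limma adjusted p = 5.66e-12). It was detected on all 6 Art:Nfkb2-labelled arrays and on none of the other 12. Whether this signal is RNA of the Pgk1 gene itself was not tested. The glycolysis list was higher by a median of 0.22 (1 of 14 higher, 3 adjusted over the list alone; adjusted p = 2.01e-05; adjusted p = 0.111 with an estimated correlation), and without Pgk1, a choice made after the data were seen, by 0.20 (adjusted p = 0.00374; adjusted p = 0.262 with an estimated correlation). Foxq1, a forkhead factor, Pglyrp1, a peptidoglycan-binding protein of granulocytes, and Il9r, the interleukin 9 receptor, were at least 5.60-fold, 8.74-fold and 3.30-fold higher. Ctse, an endosomal protease, was 13.01-fold higher (adjusted p = 2.07e-07), and Timmdc1, a mitochondrial assembly factor, and Rhbdf1, a rhomboid protein, were 5.76-fold and 5.29-fold higher. Camk2b was at least 2.92-fold higher and Tgfbi, a matrix protein of macrophages among other cells, at least 1.95-fold. Without the Y-positive culture Tgfbi had an adjusted p of 0.0523.

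Altogether 337 genes differed between Art:Nfkb2-labelled and Art-labelled withdrawn cells, 150 higher and 187 lower, and 148 by at least 2-fold (60 higher, 88 lower). The count was 215 without Art-labelled withdrawn array 3, and median scaling moved the higher share from 44.5% to 56.6%.

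**Figure D3:**
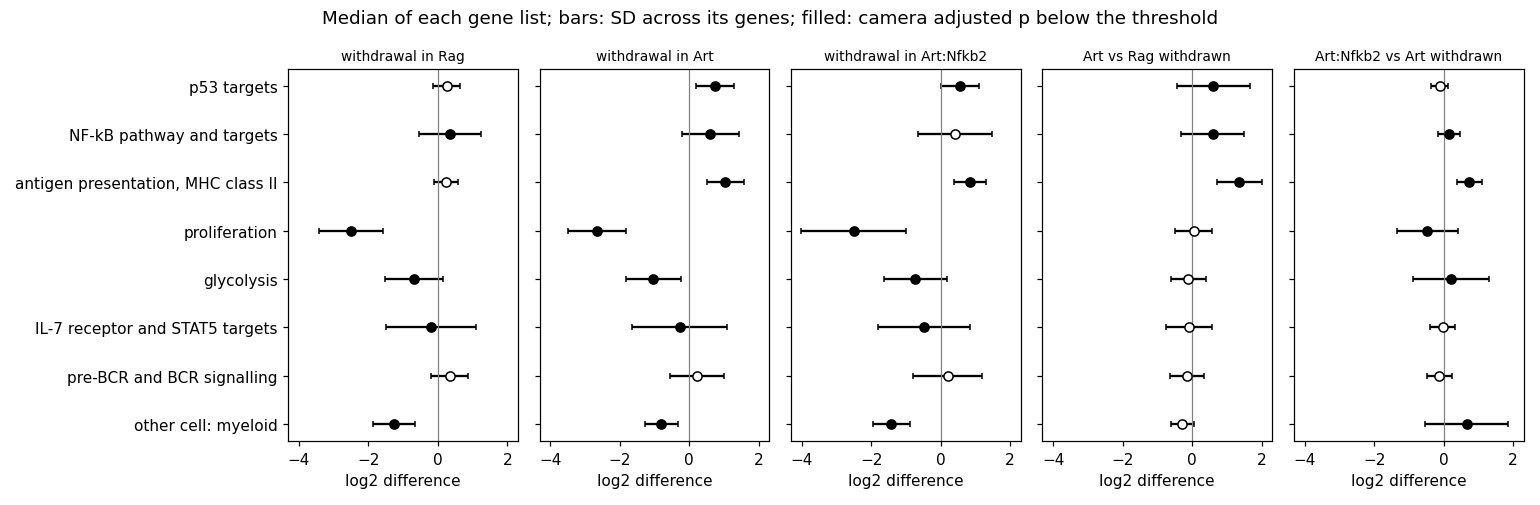
Median log2 difference of 8 gene lists in 5 comparisons, with bars of 1 SD across the list's genes, filled where the camera adjusted p is below 0.05. The NF-kB and p53 medians lie at 0.59 and 0.60 between Art-labelled and Rag-labelled withdrawn cells and at 0.16 and -0.11 between Art:Nfkb2-labelled and Art-labelled withdrawn cells.

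Genes that differed one way between Art-labelled and Rag-labelled cells and the other way between Art:Nfkb2-labelled and Art-labelled cells were counted next. There were 54, of which 38 were higher in Art-labelled than in Rag-labelled cells and lower again in Art:Nfkb2-labelled cells, and 16 the reverse; 91 moved the same way in both steps (59 higher, 32 lower). Independent lists of these sizes would share 32.3 with opposite and 31.8 with the same direction. The reversed genes included Spic, at least 1.80-fold higher and then at least 1.85-fold lower, Wnt10b, Il4i1 (2.05, then -1.53) and, in the other direction, Ret (-3.30, then 1.87). Il4i1 was picked here after its values were seen. Simulated groups without effects, sharing the same Art-labelled arrays, gave 0 and 0 genes. Hardly any gene can be called where none is changed, so these are not the numbers chance gives among changed genes. The fold changes of the 2 steps correlated at -0.07 across genes, against -0.50 in the simulation. Their covariance was -0.01 against -0.02, a difference of 0.005, and genes are not independent replicates. The 3 shared Art-labelled arrays are too few to give each step at least 2 of its own, so part of any excess may come from them. Without Art-labelled withdrawn array 3 the count was 30, and without Art:Nfkb2-labelled withdrawn array 1 it was 34.

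Against Rag-labelled cells, withdrawn Art:Nfkb2-labelled cells also had higher NF-kB and p53 target genes. Bcl3 was higher by 2.95, Cd40 by 2.06, Pim2 by 1.93 and Swap70 by 1.48. Nfkb2 read higher by 1.65, but it is lost by label in Art:Nfkb2-labelled cells, so its value does not speak to NF-kB activity. Of 31 NF-kB genes 17 were higher and 2 lower (20 and 2 adjusted over the list alone; median 0.87, adjusted p = 1.19e-08), and of 28 p53 targets 18 and 3 (0.70, adjusted p = 1.82e-07). MHC class II genes were higher in 10 of 12 (12 adjusted over the list alone; median 2.05, adjusted p = 7.29e-11) and adhesion genes in 8 of 15, with 1 lower (1.05, adjusted p = 0.00442). The calls of these 4 lists held with an estimated correlation (adjusted p = 0.017, 0.0242, 0.0335 and 0.0369). Of 17 myeloid markers 3 were higher beside the MHC class II genes (2 adjusted over the list alone; median 0.65, or 0 with undetected genes at their bound), and camera did not call them (adjusted p = 0.125). They were called without Rag-labelled withdrawn array 3 (0.0283) or Art:Nfkb2-labelled withdrawn array 2 (0.0374). Proliferation genes were lower in 15 of 30 and higher in 1 (median -0.61, or -0.28 with undetected genes at their bound, adjusted p = 0.000405; adjusted p = 0.385 with an estimated correlation). Syk differed by -0.47 (adjusted p = 0.0294), a call lost without Rag-labelled withdrawn array 3 (0.127) and without Art:Nfkb2-labelled withdrawn array 1 (0.155) or 3 (0.0935). In total 2158 genes differed (1064 higher, 1094 lower; the higher share of 49.3% was 58.9% under median scaling), and 1263 of the 1265 shared with the Art-labelled comparison had the same sign, where independent lists would share 205.1. Their fold changes correlated at 0.80 against 0.50 in the simulation, with a covariance of 0.24 against 0.02.

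Already in IL-7, Art-labelled cells had more NF-kB and p53 target RNA than Rag-labelled cells. Cd80 was higher by 2.66, Ltb by 2.33, Phlda3 by 2.14, Bcl3 by 2.11, Pim2 by 1.95, Cdkn1a by 1.45 and Nfkb2 by 1.04. Rag1, lost by label in Rag-labelled cells, was lower at -2.16. Of 28 p53 targets 13 were higher and 2 lower (17 and 2 adjusted over the list alone; median 0.66, adjusted p = 2e-07; adjusted p = 0.0207 with an estimated correlation). Of 31 NF-kB genes 10 were higher and 1 lower (15 and 3 adjusted over the list alone; median 0.32, or 0.20 with undetected genes at their bound, adjusted p = 1.97e-06; adjusted p = 0.0207 with an estimated correlation). MHC class II genes were higher in 3 of 12 (0.41, adjusted p = 0.000129; adjusted p = 0.241 with an estimated correlation), and pre-B differentiation genes lower in 5 of 23 and higher in 1 (-0.29, adjusted p = 0.0011; adjusted p = 0.139 with an estimated correlation). Camera also called the myeloid markers lower (median -0.78, or -0.70 with undetected genes at their bound, adjusted p = 0.00264; adjusted p = 0.604 with an estimated correlation), while limma called 0 of 17, and 6 were lower at an unadjusted p under 0.05. The list's call was lost without Rag-labelled IL-7 array 3 (0.0996). Proliferation (median 0.15, adjusted p = 0.0435), glycolysis (0.17, 0.0239), BCL2 family (0.02, 0.0276) and interferon-stimulated genes (0.17, 0.0471) were also called higher. With an estimated correlation these were adjusted p = 0.656, 0.456, 0.104 and 0.604. Without Rag-labelled IL-7 array 1 they were 0.756, 0.705, 0.0636 and 0.423. Other single arrays also ended these calls: Rag-labelled IL-7 array 2 for BCL2 (0.0746) and array 3 for proliferation (0.0886), Art-labelled IL-7 array 1 for proliferation (0.078), array 2 for interferon-stimulated genes (0.0746), and array 3 for proliferation (0.17), glycolysis (0.117) and interferon-stimulated genes (0.17). The BCL2 median was -0.096 under median scaling. Syk differed by -0.53 (adjusted p = 0.0491), and the call was lost without any 1 of the Rag-labelled or Art-labelled IL-7 arrays (adjusted p up to 0.181). In all 546 genes differed, 307 higher and 239 lower. All 417 that were also called after withdrawal had the same sign. Independent lists would share 52.4, but the arrays in IL-7 and after withdrawal came from the same cultures, which that value leaves out. The count was 314 without Rag-labelled IL-7 array 3, 361 without Art-labelled IL-7 array 2 and 343 without array 3, and 248 on the arrays of these groups alone. Median scaling moved the median of all genes from -0.01 to -0.15 and the higher share from 56.2% to 33.9%.

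Between Art:Nfkb2-labelled and Art-labelled cells in IL-7, 8 of 17 myeloid markers and 7 of 12 MHC class II genes were higher, and both camera calls were lost with an estimated correlation (adjusted p = 0.199 and 0.0853). Fcgr3 was higher by 3.39 (adjusted p = 3.82e-05), and the complement gene C1qa, which macrophages make, was at least 2.73-fold higher. Myeloid markers were higher in 8 of 17 (12 adjusted over the list alone; median 1.33, or 1.04 with undetected genes at their bound, camera adjusted p = 3.1e-09; adjusted p = 0.199 with an estimated correlation). MHC class II genes were higher in 7 of 12 (9 adjusted over the list alone; 0.98, adjusted p = 3.42e-09; adjusted p = 0.0853 with an estimated correlation). NF-kB genes were higher in 5 of 31 (15 adjusted over the list alone), at a median of 0.41 (camera adjusted p = 7.2e-10). This call held with an estimated correlation (adjusted p = 0.0104), which does not separate it from the higher myeloid markers of the same cells. Interferon-stimulated genes were higher in 2 of 21 (adjusted p = 0.00037; adjusted p = 0.218 with an estimated correlation) and proliferation genes lower in 2 of 30 (-0.34, adjusted p = 2.4e-07; adjusted p = 0.218 with an estimated correlation). Pre-B differentiation genes were higher in 4 of 23 (0.15, adjusted p = 0.00162; adjusted p = 0.196 with an estimated correlation) and adhesion genes in 2 of 15 (0.32, adjusted p = 0.00237; adjusted p = 0.0727 with an estimated correlation). NK-cell markers were higher in 1 of 3 (0.52, adjusted p = 0.0163; adjusted p = 0.196 with an estimated correlation), a call lost without Art-labelled IL-7 array 1 (0.0654). The mean centred signal of the myeloid markers was 1.26 ± 0.51 (SD, n = 3) in these Art:Nfkb2-labelled cells, -0.17 ± 0.19 in Art-labelled and 0.58 ± 0.85 in Rag-labelled cells; after withdrawal it was -0.06 ± 0.39, -0.94 ± 0.07 and -0.66 ± 0.84. In all 371 genes differed, 254 higher and 117 lower. Without Art-labelled IL-7 array 1, 2 or 3 there were 216, 247 and 210, and without Art:Nfkb2-labelled IL-7 array 1 or 3 there were 187 and 208. The count was 197 without the Y-positive culture and 120 with the myeloid covariate, both chosen after the data were seen.

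Whether the withdrawal response itself differed between genotypes was tested as an interaction. The response was higher in Art-labelled than in Rag-labelled cells for MHC class II genes (median 0.84, adjusted p = 0.000146) and p53 targets (0.35, adjusted p = 0.000146). Both lists had an adjusted p = 0.276 with an estimated correlation. Of their members limma called only 1 of 12 and 2 of 28, all higher, and adjusted over the list alone 6 class II genes were higher and 9 p53 targets higher and 3 lower. Spic passed the test (adjusted p = 0.000653), but it was detected only in Art-labelled withdrawn cells among these groups, so the size of the difference was not measured. Bcl3 (0.49, adjusted p = 0.326) and Syk (-0.05, adjusted p = 0.959) did not differ by this test. In all 107 genes differed, 66 with the higher response in Art-labelled cells and 41 with the lower. With each culture as a block, whose arrays deviate together, there were 363, and camera also called adhesion (adjusted p = 0.0146), myeloid (0.00109) and erythroid markers (0.0204). With an estimated correlation, run without the block, these were adjusted p = 0.276, 0.727 and 0.276. The count was 59 and 54 without IL-7 array 3 of Rag-labelled or Art-labelled cells, 58 and 67 without Art-labelled withdrawn array 1 or 2, and 177 and 170 without Rag-labelled array 1 in IL-7 or after withdrawal. Between Art:Nfkb2-labelled and Art-labelled cells 18 genes differed, 9 in each direction, among them the spindle motor genes Kif18b (-2.24) and Kif11, with lower responses, and Il9r, with a higher one (adjusted p = 0.00843 for each). Blocked by culture there were 92, and Spic (adjusted p = 0.088) was then called (0.0473), while mature B-cell markers were not (0.0882, against 0.0295). Leaving out 1 array gave 6, 8 and 7 without Art-labelled IL-7 arrays 1 to 3, 6, 10 and 10 without the Art:Nfkb2-labelled IL-7 arrays, 7 without Art-labelled withdrawn array 2 or 3, and 4, 5 and 9 without the Art:Nfkb2-labelled withdrawn arrays. Median scaling moved the medians of all genes from 0.01 to 0.11 and from -0.02 to 0.09 for these interactions. It moved the higher shares from 61.7% to 77.2% and from 50% to 37.5%, and the latter was 70% without background correction and 35.7% in the deposited matrix.

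Markers of other cell types were read in the same way. On withdrawal 9, 3 and 10 of 17 myeloid markers fell in Rag-labelled, Art-labelled and Art:Nfkb2-labelled cells (medians -1.26, -0.81 and -1.42, or -0.95, -0.19 and -0.92 with undetected genes at their bound, adjusted p = 0.0026, 0.0358 and 0.000898), among them Cd14, a monocyte receptor, by 2.14 in Rag-labelled cells. With an estimated correlation these were adjusted p = 0.505, 0.7 and 0.346, and the Art-labelled call was lost without IL-7 array 1 (0.0747) or 2 (0.0609) or withdrawn array 1 (0.0501) or 2 (0.0592). Between Art-labelled and Rag-labelled withdrawn cells camera gave adjusted p of 0.939 for T cells (1 gene), 0.716 for NK cells (3), 0.531 for erythroid and megakaryocyte genes (3), 0.963 for mast cells and basophils (1), 0.322 for stroma (2), 0.272 for mature B cells (9) and 0.0689 for early progenitors (3). Xist was detected on 10 arrays, all Art-labelled ones and those of Art:Nfkb2-labelled cultures 1 and 2. The Y-linked Eif2s3y and Kdm5d were detected on the other 8, all Rag-labelled ones and those of Art:Nfkb2-labelled culture 3.

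**Figure D4:**
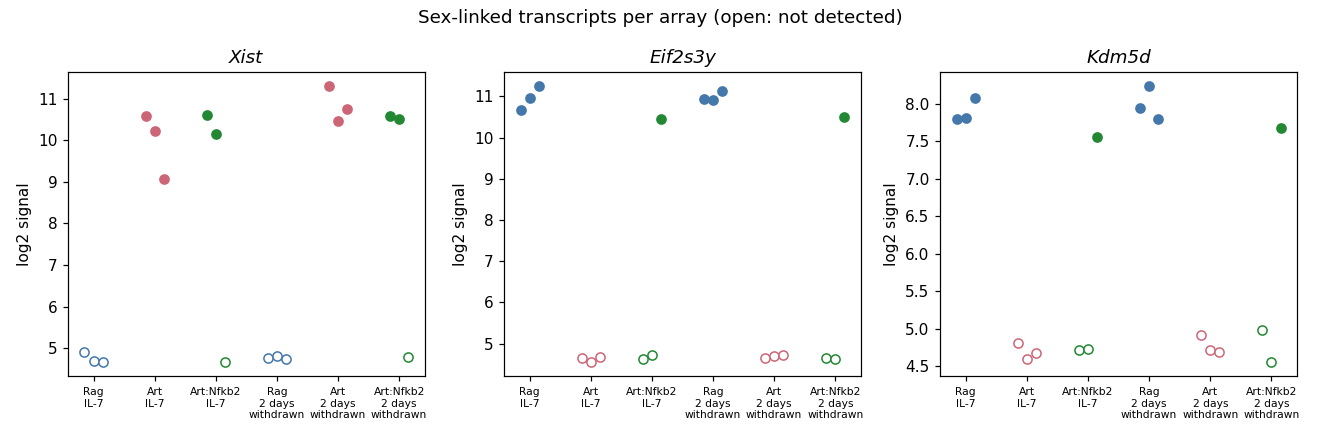
Normalized log2 signal of Xist, Eif2s3y and Kdm5d on each of the 18 arrays by genotype label, filled where detected. Xist is detected on 10 arrays at 9.08 to 11.31, and Eif2s3y (10.46 to 11.26) and Kdm5d (7.56 to 8.24) on the other 8.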

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

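The tests of neighbouring genes and the settings without the Y-positive culture, with the myeloid covariate and without Pgk1 were chosen after the results were seen. Results stand here because the withdrawal response differed between genotypes by the interaction test.

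Between Art-labelled and Rag-labelled cells 107 genes responded differently to withdrawal, and 363 with each culture as a block. The values and lost calls below are those of the fit without the block unless stated. Higher responses in Art-labelled cells were those of Trp63, a p53 relative (1.99, limma adjusted p = 0.0205), Mgmt, which removes alkyl groups from DNA (1.94, 0.0201), Tk1 (1.92, 0.00257), Lrp4 (1.87, 0.00299), Ass1, of arginine synthesis (1.84, 0.0102), and Spic (1.76, 0.000653). Lower responses were those of Asb2 (-2.93, 0.00788), Rsph1, a ciliary protein gene (-2.07, 0.00616), the unnamed probe ILMN_2742861 (-2.01, 0.00588), Hmces, a shield of abasic DNA sites (-1.76, 0.00337), and Rcan2 (-1.73, 0.00747). Trp63 lost its call without Rag-labelled withdrawn array 3 (0.0506). The values of Spic, Lrp4, Mgmt, Rcan2 and Trp63 are fitted against at least 1 group with no detected array, so they are not measured sizes. List medians were 0.84 for MHC class II, 0.35 for p53 (both adjusted p = 0.000146) and 0.26 for NF-kB genes (0.0212), all with an adjusted p = 0.276 with an estimated correlation. Of their members limma called 1 of 12, 2 of 28 and 0 of 31 (5 higher and 1 lower NF-kB genes at an unadjusted p under 0.05). The NF-kB call was lost without Rag-labelled IL-7 array 3 (0.0679), Art-labelled IL-7 array 3 (0.0991) or Rag-labelled withdrawn array 1 (0.22).

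Between Art:Nfkb2-labelled and Art-labelled cells 18 genes responded differently, and 92 with each culture as a block. Lower responses were those of Kif18b (-2.24) and Kif11 (-1.79, both adjusted p = 0.00843), Kif2c (-2.07, 0.0155), the collagenase gene Mmp13 (-2.01, 0.0268) and Nusap1 (-1.82, 0.0117). Higher ones were those of Il9r (1.63, 0.00843), the collagen gene Col26a1 (1.49, 0.0155), Tk1 (1.38, 0.0355), the phosphate transporter gene Slc20a1 (1.18, 0.0338) and Pgk1 (0.98, 0.0353). The values of Kif11, Kif2c, Mmp13, Il9r, Col26a1, Slc20a1 and Pgk1 are fitted against at least 1 group with no detected array and are not measured sizes. Col26a1 lost its call without Art-labelled withdrawn array 2 (0.0537) or Art:Nfkb2-labelled withdrawn array 1 (0.0614) or 2 (0.0673), and Kif2c without Art-labelled IL-7 array 1 (0.0536) or Art:Nfkb2-labelled withdrawn array 1 (0.0614). Tk1 lost it without any 1 of the 12 arrays compared (0.0529 to 0.129). Pgk1 lost it without any of them but Art-labelled IL-7 array 2 and withdrawn array 1 (0.0676 to 0.12). Slc20a1 lost it without any of them but Art-labelled withdrawn arrays 1 and 2 and Art:Nfkb2-labelled IL-7 array 3 (0.0711 to 0.0945). Mmp13 lost it without any of them but Art-labelled withdrawn arrays 1 and 2 and Art:Nfkb2-labelled IL-7 arrays 2 and 3 (0.0604 to 0.0966).

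List medians for that difference were -0.30 for NF-kB (adjusted p = 2.01e-05; adjusted p = 0.0561 with an estimated correlation) and 0.34 for glycolysis (1.32e-08; adjusted p = 0.0561 with an estimated correlation), the latter 0.33 without Pgk1. They were -0.57 for myeloid (0.0112; adjusted p = 0.684 with an estimated correlation), -1.01 for NK (0.00211; adjusted p = 0.084 with an estimated correlation) and 0.18 for mature B-cell markers (0.0295; adjusted p = 0.084 with an estimated correlation). Of their members limma called 1 of 14 glycolysis genes, Pgk1 itself, and 0 of 31 NF-kB genes, 17 myeloid, 3 NK and 9 mature B-cell markers. At an unadjusted p under 0.05 there were 8 lower NF-kB genes, 2 lower myeloid and 2 lower NK markers and 3 higher mature B-cell markers. The myeloid call was lost without Art:Nfkb2-labelled IL-7 array 3 (0.138) or withdrawn array 2 (0.106). The mature B call was lost without Art-labelled IL-7 array 1 (0.107) or 2 (0.0579) or withdrawn array 3 (0.0939), without Art:Nfkb2-labelled IL-7 array 3 (0.0572) or withdrawn array 2 (0.0516), and with culture as a block (0.0882).

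For each of the 10 comparisons there were 10 splits of the arrays, too few for a share under 0.05, and 1 split, the real one, gave as many genes. On withdrawal the real counts were 3753, 3803 and 3428 in Rag-labelled, Art-labelled and Art:Nfkb2-labelled cells and the highest others 232, 1 and 1. For 1607, 337 and 2158 genes between withdrawn genotypes, 546 and 371 in IL-7, and 107 and 18 in the interactions the highest other was 0. Of 100 splits for the reversed genes 4 gave at least 54, the real one included, a share under 0.05, and the highest other gave 1259. That points to a structure of the samples: Rag-labelled cells differ from both other genotypes in 1263 genes with the same sign. The splits therefore do not settle whether chance gives 54.

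The Art-labelled cultures carried Xist signal and the Rag-labelled ones Y-linked signal, so a sex difference between the cultures may account for part of the 1607 genes. Genes on the X or Y chromosome made up 46 of 1477 called genes with a known chromosome (3.11%), against 239 of 7770 tested (3.08%). Over 1431 autosomal called genes, the Y-positive Art:Nfkb2-labelled culture lay at 1.014 of the way from Rag-labelled to Art-labelled cells and the others at 1.014 and 1.018, a gap of 0.002 of that difference. A gap of at least 0.5 was set as the mark of a sex effect, but with only 1 Y-positive culture the explanation stays open, beside the genotype itself.

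Myeloid cells in the cultures may bring MHC class II RNA, since their markers were higher with these genes in Art:Nfkb2-labelled cells. The mean of 12 class II genes was higher by 0.72 ± 0.17 (SE) than in Art-labelled withdrawn cells, and by 0.57 ± 0.17 with the mean of 16 myeloid markers as a covariate (slope 0.17 ± 0.10). By the limit set for this test, the remaining difference went against myeloid cells as the whole source. The test cannot decide it, though. Of the 17 listed markers, 10 were not detected in a group of this comparison, so the covariate may correct too little. Part or all of the difference may still come from myeloid cells, and the genotype stays open as a hypothesis. Whether strain differences on the mixed background account for any of it was not tested.

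Genes near the targeted loci were called more often than elsewhere, and DNA of another strain carried along with a targeted locus may account for it. Of the 20 tested genes nearest to Rag1, 9 were called between Art-labelled and Rag-labelled withdrawn cells. Among tested genes with a known position the share called was 18.99%, and 1.85% of 7386 windows held as many. Of the 20 nearest to Nfkb2, 5 were called between Art:Nfkb2-labelled and Art-labelled withdrawn cells. The share called among tested genes with a known position was 4.05%, and 1.22% of 7387 windows held as many. Both values go with that explanation; an effect of the genotype on these genes was not tested apart from it.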

How the results depend on the processing

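The settings without the Y-positive culture, with the myeloid covariate and without Pgk1 were chosen after the data were seen. Among named genes, 6152 values kept direction and side of the threshold under other settings, 342 lost the call, 11 gained it and 1 reversed; leaving out 1 array gave 2987, 415 and 6. For gene lists these were 2238, 112, 63 and 2 reversed, and 1440, 45 and 27. Median scaling turned Vav2 on withdrawal in Art:Nfkb2-labelled cells to 0.34 (from -0.38), the BCL2 family list between Art-labelled and Rag-labelled cells in IL-7 to -0.096 (from 0.02) and the proliferation list in the Art:Nfkb2 minus Art interaction to 0.018 (from -0.06). It gave 246 genes for Art:Nfkb2-labelled against Art-labelled cells in IL-7 and 57 and 8 for the interactions. The Art:Nfkb2 minus Art interaction gave 10 without background correction and 11 without a filter. Array weights gave 757 and 602 for Art:Nfkb2-labelled against Art-labelled cells after withdrawal and in IL-7, 55 for that interaction and 112 reversed genes. The cause was not tested. With only the compared groups counts were 2094 for withdrawal in Rag-labelled cells, 980 and 248 for Art-labelled against Rag-labelled cells after withdrawal and in IL-7, and 42 and 39 for the interactions, the latter above the 18 reported; the cause was not tested. Without the Y-positive culture, again fewer samples, they were 2261 for withdrawal in Art:Nfkb2-labelled cells, 197 against Art-labelled cells in IL-7 and 4 for the interaction; with the myeloid covariate 2243 and 120.

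Leaving out 1 array gave 314 (without Rag-labelled IL-7 array 3) to 678 (array 1) for Art-labelled against Rag-labelled cells in IL-7. For Art:Nfkb2-labelled against Art-labelled cells it gave 187 (IL-7 array 1) to 258 (array 2) in IL-7 and 215 to 259 (Art-labelled arrays 3 and 2) after withdrawal. Interactions ranged from 54 (Art-labelled IL-7 array 3) to 177 (Rag-labelled IL-7 array 1) and from 4 (Art:Nfkb2-labelled withdrawn array 1) to 19 (Art-labelled withdrawn array 1), and reversed genes from 30 (Art-labelled withdrawn array 3) to 77 (Rag-labelled withdrawn array 2). The other counts stayed within 1.5 times.

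With the culture as a replicate block the interactions gave 363 and 92 genes, and as a random block 438 and 88 (correlation 0.349). The block gave Irgm1 on withdrawal in Art-labelled cells an adjusted p of 0.0651 and interferon-stimulated genes there 0.0486. With an estimated correlation, run without the block, that list had a camera adjusted p of 0.631. Beyond Irgm1, this list and the calls given with the interactions, the block changed no other within-genotype call. Between genotypes same-numbered arrays share only a number (correlations -0.28 to 0.34, 6 of 18 best with their own). There the block gave adjusted p of 0.0531 for Efna5, 0.0545 for Pfkp, 0.0609 for Syk in IL-7, 0.0494 for the pre-B-cell receptor list between Art:Nfkb2-labelled and Rag-labelled withdrawn cells and 0.0655 for interferon-stimulated genes between Art-labelled and Rag-labelled cells in IL-7. A slide block was not run, as no slide was given, and lists were not rerun for all probes, array weights or the random block. With 39.3% to 42.4% of probes detected, signal over background limits dim genes, whose differences are understated.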

Other observations

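The myeloid covariate was chosen after the data were seen, and the single-gene patterns in the last paragraph were picked from the data and not tested. Genes of interferon response fell on withdrawal in part. Gbp2, a guanylate-binding protein of host defence, changed by -1.79, -1.95 and -2.02 in Rag-labelled, Art-labelled and Art:Nfkb2-labelled cells, and Gbp3, of the same family, by -1.88, -1.50 and -1.48. Ifi47, an immunity-related GTPase, changed by -0.97, -0.83 and -1.08. Of 21 interferon-stimulated genes 5, 8 and 8 fell and 2, 3 and 2 rose. Camera called the list in Art:Nfkb2-labelled cells (median -0.46, or -0.26 with undetected genes at their bound, adjusted p = 0.00728; adjusted p = 0.332 with an estimated correlation), but not in Rag-labelled (0.221) or Art-labelled cells (0.0855). Fry called it in Art-labelled (adjusted p = 0.0461) but not in Rag-labelled cells (0.0946). With the myeloid covariate the Art:Nfkb2-labelled list had an adjusted p of 0.203.

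DNA break repair genes went both ways on withdrawal. Of 17 tested, 4, 4 and 6 rose and 6, 5 and 4 fell, and camera gave adjusted p of 0.492, 0.376 and 0.597. Fry, which does not set a list against the other genes, gave adjusted p of 1.2e-05, 2.11e-06 and 0.000212. H2ax, the histone variant that marks breaks, changed by -2.28, -2.60 and -2.51, and Brca2, of homologous recombination, by -0.99, -0.85 and -0.68. Polm, a polymerase of end joining, rose by 0.69, 0.69 and 0.70, and Trp53bp1, which favours end joining, by 0.53, 0.60 and 0.36.

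The Pgk1 probe read 8.18 to 9.10 on the 6 Art:Nfkb2-labelled arrays and at most 5.39 on the others. Fcer1g, an Fc receptor chain of myeloid cells, was detected on 16 arrays at 9.02 to 11.58, and on neither array of Art:Nfkb2-labelled culture 1 (at most 4.67). Erdr1, a gene of the region shared by X and Y, ranged from 6.40 to 13.07 over the 18 arrays.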
